A study of Mus musculus with 2 samples.

How the data were processed

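DPPA2 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in R1/E mouse embryonic stem cells, in 1 untreated library and 1 library made after 8 h of adriamycin, so that each group had 1 library. Groups were taken from the sample labels. The labels gave both libraries the same batch entry. The treated sample's genotype field holds its treatment, and its group was therefore taken from its title.

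The submitters' processing notes name FastQC 0.12.1, Bowtie2 2.5.1, SAMtools, MACS3 3.0.0b1 and deepTools 3.5.1, and the mouse build mm10. Filters, the calling command and the use of an input control are not given in the sources used here. Each library had its own deposited peak list, called per library with no pooling. The fold enrichment of each peak is the authors' caller's own ratio of summit over local background, as deposited, and it is not scaled between libraries. The deposited −log10 p and −log10 q are the authors' values for the same summit. The smallest −log10 q was 1.33 in the untreated list and 1.30 in the adriamycin list. The deposited score equalled 10 times −log10 q, cut to a whole number, for 99.97% and 100.0% of entries. A further deposited value, of another kind, gives the distance in bp from the peak start to the summit.

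Peaks on chromosomes 1 to 19, X and Y were used. Peaks on unplaced contigs (123 untreated, 136 adriamycin) and on the mitochondrial genome (3 and 6) were counted and left out of the comparisons. Neither list held a repeated region, so each entry was 1 peak.

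The lists carry no read totals. The depth behind a peak was therefore recovered from its fold and −log10 p, by searching for the whole number of fragments at the summit that gives both values, with a pseudocount of 1 on summit and background and a Poisson upper tail. A peak counted as recovered when −log10 p matched within 0.001. This gave a whole number for 99.8% of untreated and 99.9% of adriamycin entries, against 0.572% and 0.788% with the other definition of the tail. The lowest background recovered, taken as the genome-wide background, was 1.19 fragments in the untreated and 1.03 in the adriamycin library. Local backgrounds above it were whole multiples of 0.02 (within 0.0004) for 99.97% and 99.99% of peaks, the step that 200 bp fragments in a 10000 bp window give. Such steps arise where a ChIP library serves as its own background, in which case the folds and the concentration at gene ends carry no correction for input. This is read from the values and is stated in none of the sources used here. Local background was called high from 5 times the genome-wide value upward, a limit chosen after the data were seen. If a library serves as its own background, this value includes the peak's own fragments, and a strong peak can pass the limit by them. The few peaks that were not recovered were treated as high background.

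Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the same build as mm10, with 21887 protein-coding genes on the chromosomes used. The table gives each gene's start and end without strand, exons or sequence. The planned promoter window of 1000 bp around a transcription start site was therefore replaced by 1000 bp around either end of the gene, and a gene-end peak can lie at the start or at the far end of a gene. Exon and intron classes became "inside a gene" and "between genes". Matching on CpG content, base composition at summits and the search for p53 response elements need sequence and were not run.

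Peak lists were compared with bedtools 2.31.1 by an overlap of at least 1 bp, beside 100 seeded shuffles of the untreated list within its chromosomes. Shares of summits were set beside 100000 random positions drawn from the same chromosomes in each library's proportions. Each of 12 gene lists was set beside 10000 random lists of the same size from all protein-coding genes. A list was called above or below random lists when at most 250 of the 10000 had as many, or as few, members with a peak. In the 2-cell list 3 symbols (Zscan4a, Zscan4e and Eif1ad8) had no protein-coding entry, which left 29 of its 32 members. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

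Intervals are 95% intervals, exact Clopper-Pearson for shares and exact Poisson for pileups. They cover counting error only, and a summit is by construction the highest position of its peak. With 1 library per group there was no test between the groups, no p-value and no estimate of replicate spread.

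Tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, apart from the replacements given above and the additions named in the closing section. The planned random lists were matched on promoter CpG content, and the unmatched random lists used for the main values replaced them. Named genes are 7 chosen in every case (Dppa2, Dppa4, Trp53, Cdkn1a, Mdm2, Bbc3, Pmaip1), the 5 strongest by rank of fold with a gene-end peak in both lists, the 5 strongest by fold in each list and not in the other, up to 4 members per gene list by fold, and the 3 strongest peaks of each list. Other members of the lists are named, without selection by value, where the members with a peak are given. A few genes are not reported here. Liver and blood genes, olfactory receptors and ribosomal proteins are given as counts.

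The alternatives were a q of at most 1e-05, a fold of at least 5, lists of equal length, the strongest 1000 peaks, a reciprocal overlap of 50%, summits within 250 bp, gene-end windows of 500 and 2500 bp, and any overlap of a peak with the window. On simulated data, 100% of 2000 pileups were recovered, a planted overlap of 60% was found as 60.1%, and 100% of 2000 genes given a gene-end peak were found. A planted list with 20 of 40 members carrying a peak was reached by 0 random lists, and 1% of 200 unplanted lists of 40 genes were called above random lists.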

Results

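DPPA2, a DNA-binding protein of pluripotent and germline cells that acts with its partner DPPA4, was mapped by ChIP-seq in R1/E cells. R1/E is a mouse embryonic stem cell line, here wild type for p53 and grown on gelatin with leukemia inhibitory factor. There was 1 library from untreated cells and 1 from cells given adriamycin (doxorubicin, a topoisomerase poison that breaks DNA) for 8 h. The design asks where DPPA2 is bound once DNA is damaged, and the study's title links DPPA2 to p53 and apoptosis. Neither group had a replicate, so every difference given here is one between 2 libraries. The median peak summit was covered by 14 fragments in both libraries (quartiles 12 and 18 untreated, 11 and 17 adriamycin), over a genome-wide background of 1.19 fragments untreated and 1.03 adriamycin. Fold enrichments are those of the authors' peak caller, used to rank peaks within a list; where a gene's folds in both lists are given, a difference between them shows no change. Coordinates are those of mm10.

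The first comparison was of where peaks were called with and without adriamycin. The adriamycin list held 16229 peaks covering 5.78 Mb and the untreated list 7043 peaks covering 2.33 Mb, 2.30 times as many peaks and 2.48 times the length. Most untreated sites were called again: 5613 untreated peaks (79.7%, interval 78.7 to 80.6%) overlapped an adriamycin peak, whereas 5584 adriamycin peaks (34.4%, 33.7 to 35.1%) overlapped an untreated one. Shuffled peaks gave an overlap of at most 0.625% and 0.277%. The highest folds lay at overlapping positions in both lists. The region at chromosome 3, 56575434 to 56575785, between genes and 391847 bp from the nearest gene end (Nbea), had a fold of 33.5 in the untreated list and its counterpart at 56575423 to 56575754 one of 34.4 in the adriamycin list. On chromosome 15 the peak at 60141698 to 60142042, 125241 bp from 4933412E24Rik, had a fold of 33.0, and its adriamycin counterpart at 60141707 to 60142038 a fold of 34.6. The third peak, at X 76598550 to 76599165 inside Cldn34d, had folds of 32.4 and 32.3. On chromosomes 3 and 15 the summit pileups were 245 and 218 fragments untreated and 219 and 236 with adriamycin, over local backgrounds of 6.34, 5.64, 5.40 and 5.84 fragments. By the limit of 5 times the genome-wide background, these counted as high local background, except the untreated peak on chromosome 15. If a library serves as its own background, a strong peak's own fragments raise that value. The limit therefore does not show that these peaks lie in high-background regions. The X peak was not recovered in either list and was treated as high background. No input profile was used here, so the highest folds may mark positions that gather reads without DPPA2.

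Peaks called in both lists were the stronger ones within each list. Their median fold was 5.40 (quartiles 4.58 and 6.49) in the untreated list, against 4.61 (4.14 and 5.24) for the 1430 untreated peaks without an adriamycin counterpart. In the adriamycin list it was 6.22 (5.09 and 7.69), against 4.80 (4.24 and 5.47) for the 10645 peaks without an untreated counterpart. Of the strongest 10% of the adriamycin list by −log10 q, 88.7% of peaks (87.1 to 90.2%) were overlapped, and of the weakest 10%, 9.80% (8.40 to 11.4%). The corresponding shares in the untreated list were 99.3% (98.4 to 99.8%) and 61.2% (57.5 to 64.8%). The shares were unequal because almost the same number of peaks overlapped in each list, while the lists differed in length. With the strongest 7043 peaks of each, 57.4% of untreated and 57.0% of adriamycin peaks overlapped, shares that equal length makes alike by construction.

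**Figure D1:**
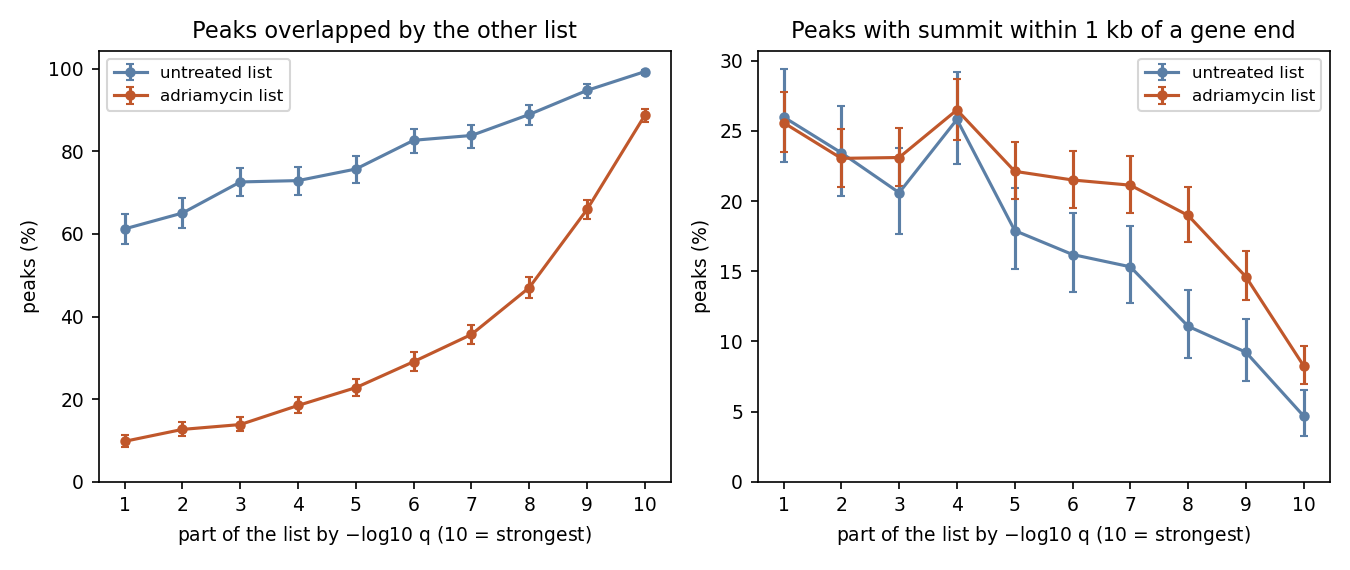
Share of peaks (%, y axes) in each of 10 equal parts of a list ordered by −log10 q (x axes, 10 the strongest) that overlapped the other list (left) or had a summit within 1 kb of a gene end (right), for the untreated list (blue) and the adriamycin list (orange). Bars are exact 95% intervals. Overlap is highest in the strongest part (99.3% and 88.7%), where the gene-end share is lowest (4.68% and 8.26%).

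The second comparison was of where the peaks lie. DPPA2 summits were concentrated at the ends of protein-coding genes in both libraries. In the untreated list 1199 summits (17.0%, 16.2 to 17.9%) lay within 1 kb of a gene end, against 3.12% of random positions, 5.46 times as many. In the adriamycin list 3324 summits did (20.5%, 19.9 to 21.1%), against 3.14%, 6.53 times as many. The concentration was highest at 100 to 250 bp from a gene end, 8.47 times random untreated and 11.5 times with adriamycin, and at 2500 to 5000 bp it was 0.924 and 1.03 times random. Further inside genes lay 31.1% of untreated summits (30.0 to 32.2%) and 34.9% of adriamycin summits (34.2 to 35.7%), below the 38.8% and 38.9% of random positions. Between genes lay 51.9% (50.7 to 53.04%) and 44.6% (43.8 to 45.4%), against 58.1% and 58.0% of random positions. Adriamycin peaks without an untreated counterpart had a gene-end share of 22.7% (21.9 to 23.5%), against 16.2% (15.2 to 17.2%) of those with one. The untreated list had the same order, with 20.3% (18.2 to 22.5%) of peaks without an adriamycin counterpart and 16.2% (15.2 to 17.2%) of those with one. The gene-end share of the adriamycin list was also higher at a q of at most 1e-05, 17.1% against 11.8% untreated. At a fold of at least 5 it was 16.2% against 10.9%. With lists of equal length the order turned, 16.5% against 17.0% untreated. There the strongest part of the adriamycin list stood beside the whole untreated list. Since the share falls with strength, that turn does not show that list length alone made the difference. No input profile was used here to set these shares against.

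**Figure D2:**
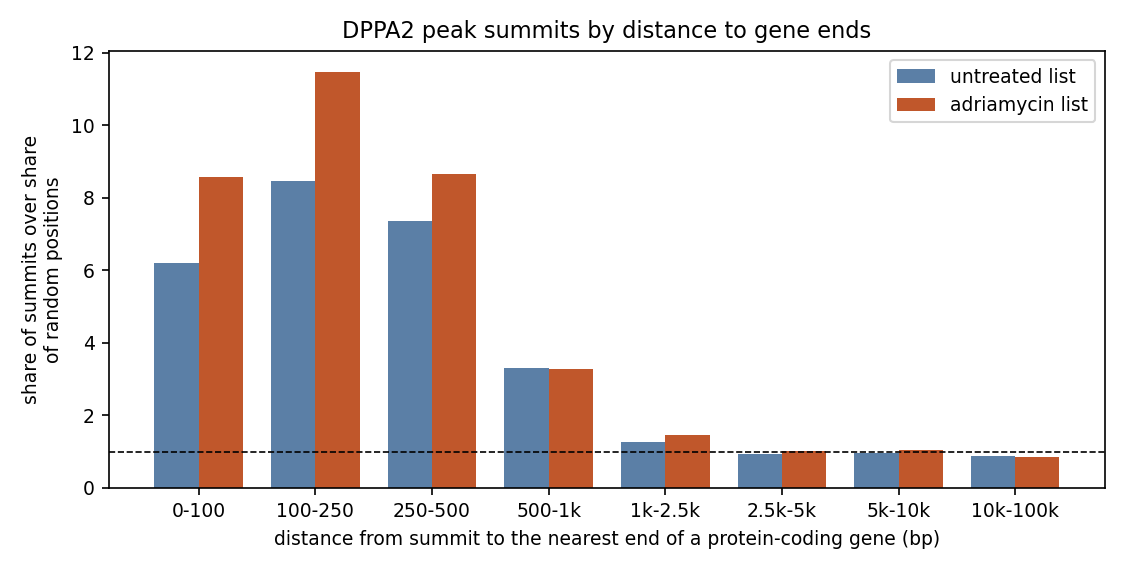
Share of peak summits over the share of random positions (y axis) by distance to the nearest end of a protein-coding gene (x axis, bp), for the untreated list (blue bars) and the adriamycin list (orange bars); the dashed line marks equality with random positions. Both lists peak at 100 to 250 bp, at 8.47 and 11.5 times random.

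The third comparison was of genes with a DPPA2 peak at an end. Of 21887 protein-coding genes, 1266 (5.78%) had one in the untreated list and 3510 (16.0%) in the adriamycin list. Both lists shared 987 genes, against 203 if the lists were independent, so that 78.0% of the untreated genes (75.6 to 80.2%) were also called with adriamycin. A further 2523 genes were called in the adriamycin list and not in the untreated list, and 279 the other way round. At equal list length these numbers were 656 and 668, with 598 genes in both.

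Among genes called in both lists the strongest by rank of fold were Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, Gm32584, Rnf41, a ubiquitin ligase gene, Vmn2r29, a vomeronasal receptor gene, and Oasl1, of the interferon-induced oligoadenylate synthetase family. Lars2 (chromosome 9, 123366927 to 123462675) had its peak at 123461792 to 123462200, inside the gene, with a fold of 30.3 and a pileup of 216 fragments (188 to 247) untreated, and a fold of 30.1 and a pileup of 184 (158 to 213) with adriamycin. The local background there was 5.17 and 5.00 times the genome-wide value, which is high local background by the limit used here. The peak's own fragments may account for part of it. Gm32584 (chromosome 5, 36630163 to 36661658) had folds of 21.9 and 24.1, with its untreated peak at 36630466 to 36630779. Rnf41 (chromosome 10, 128411616 to 128441441) had folds of 23.98 and 23.7 at a peak just outside its higher-coordinate end, 128441764 to 128442074. Vmn2r29 (chromosome 7, 7212996 to 7278289) had folds of 15.2 and 15.5, and Oasl1 (chromosome 5, 114923143 to 114937911) folds of 15.8 and 13.7. Without an input profile these folds do not by themselves show DPPA2 binding. At the 92 shared peaks of over 60 times the background, the median pileup ratio scaled to background, adriamycin over untreated, was 1.01. Over all 5603 shared peaks on the assembled chromosomes it was 1.32.

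The strongest genes in the adriamycin list and not in the untreated list had lower folds. Gm40864 (chromosome 12, 22540342 to 22623430) had a peak at 22623110 to 22623574 with a fold of 9.86 and a pileup of 19 fragments (11.4 to 29.7), and the nearest untreated summit was 73277 bp from the gene's ends. Spin2d (chromosome X, 73175302 to 73176989) had a fold of 9.31, and Alg9 (chromosome 9, 50775225 to 50843639), a glycosyltransferase gene, one of 8.82. Krt5 (chromosome 15, 101707069 to 101712905), which encodes a basal epithelial keratin, had a fold of 8.47 at 101712469 to 101712871, with the nearest untreated summit 2574 bp away. Wls (chromosome 3, 159839650 to 159938666), needed for secretion of Wnt proteins, had a fold of 8.38 at 159939406 to 159939636.

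In the untreated list and not in the adriamycin list the strongest were 9030025P20Rik (chromosome 17, 14978864 to 14991577, fold 7.35), Stimate (chromosome 14, 30825575 to 30877210, 7.29), the Fc receptor gene Fcgr3 (chromosome 1, 171051169 to 171065915, 6.67), Hectd2 (chromosome 19, 36554126 to 36621135, 6.52) and St6galnac1 (chromosome 11, 116765025 to 116775507, 6.46). For 4 of these 5 an adriamycin summit lay just beyond the 1 kb window, at 1332 bp from 9030025P20Rik, 1341 bp from Stimate, 1432 bp from Fcgr3 and 1312 bp from St6galnac1, and for Hectd2 the nearest was 144160 bp away. Over all 279 such genes, 41 (14.7%) had an adriamycin summit within 2500 bp of an end. Of the 2523 genes called in the adriamycin list and not the untreated list, 64 (2.54%) had an untreated summit that near.

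The fourth comparison was of gene groups fixed in advance. Germline genes carried gene-end peaks more often than random lists in both libraries. Of 32 germline genes 14 (43.8%) had a peak in the adriamycin list, where random lists had a median of 5 and 1 of 10000 had as many, and 6 (18.8%) had one in the untreated list, where the median was 2 and 79 of 10000 had as many. Called in both lists were Mael, Dazl, Ddx4 and Slc25a31. Called in the adriamycin list and not the untreated list were the synaptonemal complex genes Syce1, Sycp2 and Sycp3, the piRNA pathway genes Piwil2 and Mov10l1, and Tex101, Taf7l, Tex19.1, Brdt and Sohlh2. Hormad1 and Asz1 were called the other way round. Dazl (chromosome 17, 50279393 to 50293620), an RNA-binding protein gene needed for germ cells, had folds of 6.98 untreated and 7.81 with adriamycin, with pileups of 23 (14.6 to 34.5) and 24 (15.4 to 35.7) fragments at its higher-coordinate end. Brdt (chromosome 5, 107331116 to 107387061), a testis bromodomain gene, had a fold of 7.97 and a pileup of 21 (13.0 to 32.1) in the adriamycin list, 150 bp from its lower-coordinate end. Asz1 (chromosome 6, 18050964 to 18109061) had a fold of 6.10 in the untreated list. Among peaks with a q of at most 1e-05 or a fold of at least 5 the untreated list had 2 germline genes against a random median of 0 each time, and was no longer called above random lists (1412 and 1457 of 10000 had as many). With lists of equal length 7 germline genes had a peak with adriamycin and 6 untreated, both above random lists (19 and 81 of 10000 had as many).

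Wnt pathway genes carried more peaks than random lists in the adriamycin list. There 14 of 38 (36.8%) had one, against a random median of 6, and 22 of 10000 random lists had as many. In the untreated list 3 of 38 had one, against a median of 2, and 3733 random lists had as many. The receptors Fzd3 and Fzd8 were called in both lists. In the adriamycin list and not the untreated list were the ligands Wnt5b, Wnt6 and Wnt10a, the receptors Fzd1, Fzd2, Fzd6, Fzd7 and Fzd10, the co-receptors Lrp5 and Lrp6, and Axin1 and Tcf7, and the other way round was Fzd9. Axin1 (chromosome 17, 26131217 to 26195811), a scaffold of the complex that degrades beta-catenin, had a fold of 5.93 and a pileup of 15 (8.40 to 24.7). The transcription factor gene Tcf7 (chromosome 11, 52246527 to 52283383) had a fold of 5.65 and a pileup of 18 (10.7 to 28.4), and Fzd9 (chromosome 5, 135248938 to 135251047) a fold of 3.78 in the untreated list. With a fold of at least 5 there were 6 Wnt genes with adriamycin against a median of 2 (438 random lists as many), and with lists of equal length 5 against 2 (615), both short of the call. Untreated there were 3 against 2 at equal length. Of the members with a peak in the adriamycin list, 4 of 14 germline and 2 of 14 Wnt genes also had one in the untreated list, against 28.1% (26.6 to 29.6%) of all genes.

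**Figure D3:**
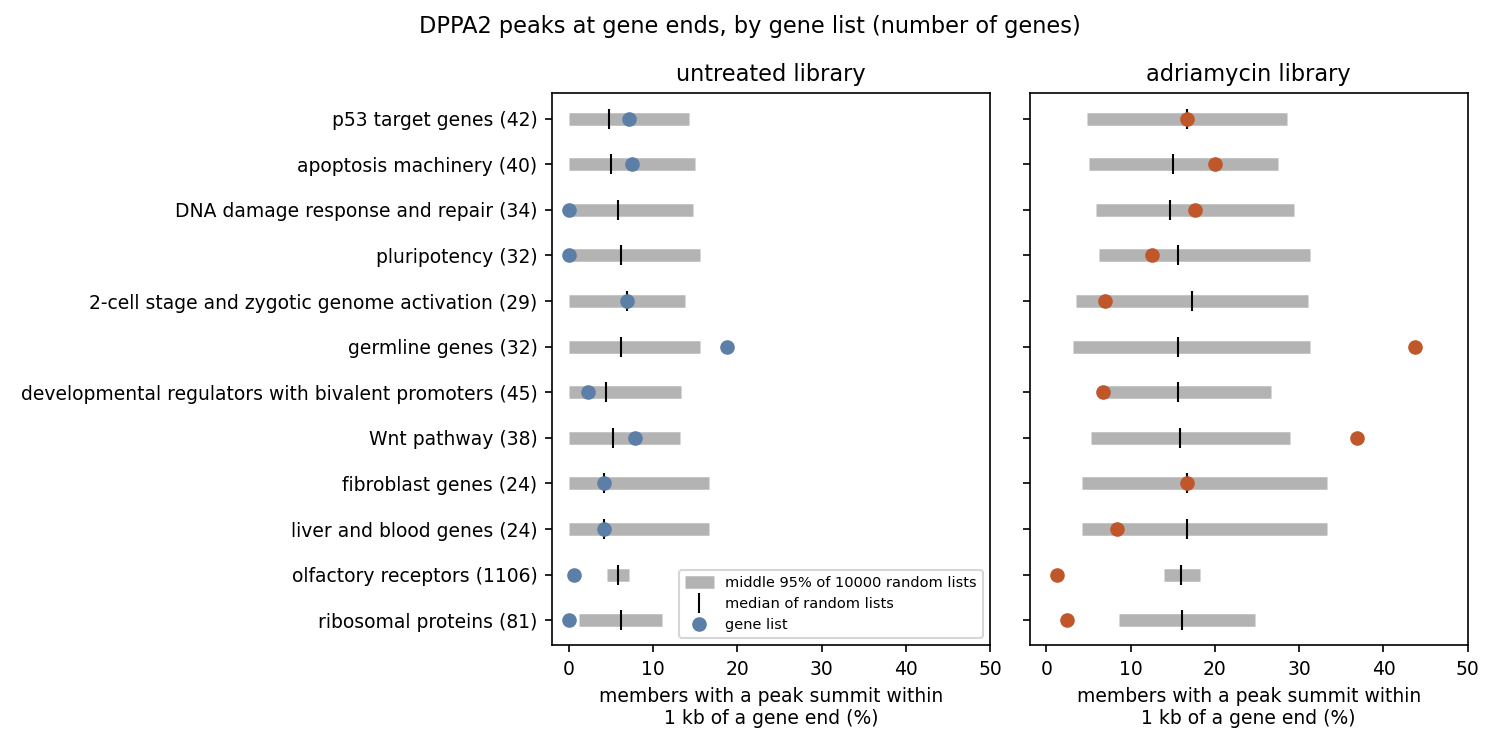
Share of each gene list's members (%, x axes) with a peak summit within 1 kb of a gene end, in the untreated list (left, blue points) and the adriamycin list (right, orange points). Grey bars span the middle 95% of 10000 random lists of the same size, black ticks are their medians and the number of genes stands in brackets; germline genes lie above the bars in both libraries (18.8% and 43.8%), and Wnt pathway genes with adriamycin (36.8%).

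p53 targets, apoptosis genes and DNA damage response genes had peaks about as often as random lists in both libraries. Of 42 p53 targets 7 had a gene-end peak in the adriamycin list and 3 in the untreated list, against random medians of 7 and 2. Ei24, Polk and Ckap2 were called in both lists, and Bbc3, Trp53inp1, Perp and Plk2 in the adriamycin list and not the untreated list. Bbc3, which encodes the pro-apoptotic protein PUMA (chromosome 7, 16308398 to 16318334), had its peak at 16317232 to 16317708, inside the gene and 959 bp from its higher-coordinate end. The fold there was 6.31 with a pileup of 24 (15.4 to 35.7), and the nearest untreated summit lay 69320 bp from the gene's ends. Ckap2 (chromosome 8, 22168149 to 22185819) had folds of 4.89 and 7.51, with pileups of 17 (9.90 to 27.2) and 25 (16.2 to 36.9). No gene-end peak was called in either list at Trp53 itself, at Cdkn1a, which encodes the cell cycle inhibitor p21, at Mdm2, which encodes the ubiquitin ligase of p53, or at Pmaip1, which encodes NOXA. The nearest adriamycin summits lay 24272 bp from an end of Trp53 (chromosome 11, 69580348 to 69591873), 58334 bp from Cdkn1a (chromosome 17, 29090979 to 29100722), 93070 bp from Mdm2 (chromosome 10, 117688875 to 117710758) and 166728 bp from Pmaip1 (chromosome 18, 66458604 to 66465558).

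Of 40 apoptosis genes 8 had a peak in the adriamycin list and 3 in the untreated list, against medians of 6 and 2. Ripk1 was called in both. Among others, Bcl2, Bid, Bbc3, Casp6, Endog and Dapk1 were called in the adriamycin list and not the untreated list, and Bok and Fasl the other way round. Ripk1 (chromosome 13, 34002225 to 34035170), a kinase of death receptor signalling, had folds of 4.36 and 5.80, and Fasl (chromosome 1, 161780691 to 161788495), the ligand of the Fas receptor, a fold of 5.00 in the untreated list. Of 34 DNA damage response genes 6 had a peak in the adriamycin list, against a median of 5, and 0 in the untreated list, where 1287 of 10000 random lists also had 0. These included Nbn, Palb2, Wee1, Cdc25a and Top2b. Top2b (chromosome 14, 16365206 to 16430787), which encodes a topoisomerase that adriamycin traps on DNA, had a fold of 5.41 and a pileup of 15 (8.40 to 24.7), and Nbn (chromosome 4, 15957587 to 15992589), of the double-strand break sensor complex, a fold of 5.26. With lists of equal length the counts with adriamycin and untreated were 4 and 3 for p53 targets, 2 and 3 for apoptosis genes, where the direction turned, and 1 and 0 for DNA damage response genes.

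Pluripotency, 2-cell and developmental genes were not above random lists in either library. Of 32 pluripotency genes 4 had a peak in the adriamycin list (Klf2, Klf5, Fgf4 and Tet2) and 0 in the untreated list, against medians of 5 and 2. Tet2 (chromosome 3, 133463677 to 133545136), a DNA demethylation enzyme gene, had a fold of 7.19 and a pileup of 20 (12.2 to 30.9), and Klf5 (chromosome 14, 99298691 to 99313412) a fold of 4.70. Dppa2 (chromosome 16, 48310274 to 48319513) and Dppa4 (chromosome 16, 48283735 to 48294292) had no gene-end peak in either list, and the nearest summits lay 62330 and 35791 bp away untreated and 84632 and 58093 bp away with adriamycin. Of 29 genes of the 2-cell stage and zygotic genome activation, Smarca5 and Gm4340 had a peak in both lists, against medians of 2 and 5. Duxf3, another member, had a peak in both lists with its summit 1109 bp from an end, so the 1 kb window left it out. With a 2500 bp window 4 members had a peak untreated and 5 with adriamycin, against medians of 2 and 6. Smarca5 (chromosome 8, 80699943 to 80739459), a chromatin remodeller gene, had folds of 3.53 and 6.73, and Gm4340 (chromosome 10, 104194042 to 104196522) of 4.92 and 4.59. Of 45 developmental regulators 3 had a peak in the adriamycin list (Mixl1, Lbx1 and Myf5) and 1 in the untreated list, against medians of 7 and 2. Myf5 (chromosome 10, 107482908 to 107486927) had a fold of 4.33 and Lbx1 (chromosome 19, 45232684 to 45236841) one of 4.14. With lists of equal length the counts with adriamycin and untreated were 1 and 0 for pluripotency genes, 1 and 2 for 2-cell genes and 0 and 1 for developmental regulators. With a 2500 bp window the developmental list was below random lists with adriamycin.

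The comparison lists were within or below the range of random lists. With lists of equal length the fibroblast genes had 1 with a peak in each library and the liver and blood genes 2 with adriamycin and 1 untreated. Of 24 fibroblast genes 4 had a peak in the adriamycin list (Col6a2, Fbn1, Twist2 and Loxl1) and 1 in the untreated list (Col6a2), against medians of 4 and 1. Col6a2 (chromosome 10, 76595756 to 76623630) had folds of 4.26 and 5.59, and Fbn1 (chromosome 2, 125300594 to 125506485) a fold of 4.76. Of 24 liver and blood genes 2 and 1 had a peak, against medians of 4 and 1. Olfactory receptor genes were below random lists in both libraries, with 14 of 1106 against a median of 177 with adriamycin and 7 against 64 untreated. Random lists matched on gene length had lower medians, 54 and 23, and the olfactory receptors were still below them. Those lists were drawn from all protein-coding genes of like length, the receptors included, which lowers their medians. Ribosomal protein genes were below as well, with 2 of 81 against a median of 13 with adriamycin and 0 against 5 untreated. Untreated, the count stayed at 0 with a q of at most 1e-05, with a fold of at least 5 and with random lists matched on gene length, against medians of 2, 2 and 3, but the list was no longer called below random lists.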

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

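The tests of the longer adriamycin list given here were chosen only after the result was seen.

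Peaks outside the assembled chromosomes were not part of the comparisons, and their number with adriamycin was above that in the untreated control. The adriamycin list held 136 peaks on unplaced contigs, against 123 untreated, and 6 on the mitochondrial genome, against 3 untreated, in whole lists of 16371 and 7169 peaks, so that they were a smaller part of the adriamycin list. At 98 such peaks called in both lists the median pileup ratio scaled to background was 0.989 (quartiles 0.903 and 1.16).

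The adriamycin list was 2.30 times as long as the untreated one on the assembled chromosomes. A deeper adriamycin library is argued against by the genome-wide background pileup, which was 0.862 times the untreated one. A higher signal over background had the values it needs at peaks in ordinary local background, but not at the strongest peaks. At shared peaks of 25 to 40 times the background, the pileup scaled to background was 1.38 times the untreated one (median; quartiles 1.16 and 1.64, 290 peaks) in ordinary local background and 1.05 times (0.949 and 1.16, 49 peaks) in high local background. At the 92 shared peaks of over 60 times the background the median was 1.01 (0.938 and 1.18). Over all 145 shared peaks in high local background it was 1.03 (0.928 and 1.16). The higher signal in ordinary local background may reflect more DPPA2 on chromatin after DNA damage or a higher yield of the immunoprecipitation. With 1 library per group both stay open. A gain greater at gene ends cannot be told apart from a uniform one, since the medians were 1.33 (1.095 and 1.57) at gene ends and 1.32 (1.07 and 1.61) elsewhere.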

How the results depend on the processing

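The removal of peaks in high local background and the matching of random lists on gene length were chosen after seeing the data. In every alternative that left list lengths free, the adriamycin list was the longer one and the untreated list the more overlapped, except that lists of equal length removed both by construction. With a q of at most 1e-05 there were 3668 untreated and 8441 adriamycin peaks, and with a fold of at least 5 there were 4051 and 8681. The overlapped shares, untreated then adriamycin, were 77.5% and 33.6% with the q limit, 76.9% and 35.8% with the fold limit, 57.4% and 57.0% at equal length, 63.8% and 27.7% with reciprocal overlap, 74.5% and 32.4% with summits within 250 bp, and 97.8% and 94.3% for the strongest 1000 peaks against the whole other list. The gene-end shares were 11.8% and 17.1% with the q limit, 10.9% and 16.2% with the fold limit, 12.1% and 15.5% with a 500 bp window and 22.1% and 26.3% with a 2500 bp window. At equal length the adriamycin share was 16.5%. Genes in both lists, in the adriamycin list and not the untreated one, and the reverse numbered 323, 1236 and 136 with the q limit, 304, 1215 and 164 with the fold limit, and 598, 656 and 668 at equal length. The number of gene lists above random lists fell to 0 untreated with the q limit and with the fold limit, and to 1 with adriamycin with the fold limit and at equal length. The q and fold limits and the equal length keep fewer peaks by construction; for the other changes the cause was not tested. The difference in median fold between overlapped and other peaks moved by less than the quartile range of folds under both other definitions of overlap. Of the counts of random lists for single gene lists, 136 lay on the main side and 8 did not. These 8 were germline untreated (1412 with the q limit, 1457 with the fold limit), Wnt with adriamycin (438 with the fold limit, 615 at equal length), developmental genes with adriamycin (91 lists with as few members with a 2500 bp window, against 550) and ribosomal proteins untreated (1824, 1731 and 449 with as few under the q limit, the fold limit and length matching, against 75). Depth limits single genes: the smallest summit pileups were 7 and 6 fragments. No paired analysis was possible because each group had 1 library and no test was made between them. Base composition at summits, p53 response elements and CpG-matched random lists, with their alternatives, were not run.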

Other observations

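The families of genes with a common symbol stem, the classes of gene, the Dux peaks and the test on open promoters were chosen only after results were seen; the tests on gene length and on high local background were set before theirs.

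Keratin genes carried gene-end peaks more often than random lists. Of 53 genes with the stem Krt, 20 had a peak in the adriamycin list, at 20 distinct peaks, against a random median of 8, and 1 of 10000 random lists had as many. In the untreated list 8 of them had one, and 105 random lists had as many. Genes of the stems Dennd (9 of 16), Galnt (9 of 17), Rnf (24 of 83), Fbxl (9 of 18) and Zdhhc (10 of 24) were also above random lists with adriamycin. In the untreated list 10 of 42 Ube genes, which encode ubiquitin-conjugating and related enzymes, had a peak and 0 of 10000 random lists had as many, while 11 had one with adriamycin, where 620 random lists had as many. Below random lists with adriamycin were the vomeronasal receptor genes (Vmn, 2 of 355), the Pramel genes (0 of 47), the beta-defensin genes (Defb, 0 of 42) and the cytochrome P450 genes (Cyp, 5 of 99). Of 144 families of at least 15 genes, 10 were above and 15 below with adriamycin, where chance gives at most about 3.6 on each side. Below, chance gives fewer, since small families such as Taar (0 of 15, 776 random lists as few) could not be called. These random lists were not matched on gene length, and short genes have less sequence within the windows at their ends.

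Among the classes of gene, gene-end peaks with adriamycin were most frequent at protein-coding genes, at 16.0% (15.6 to 16.5%) of them. Untreated, the share was 5.78% (5.48 to 6.10%), which lies inside the interval of transcribed pseudogenes, at 4.95% (3.20 to 7.27%), and above the 2.21% (1.96 to 2.48%) of long noncoding RNA genes. The adriamycin shares were 9.90% (7.39 to 12.9%) at transcribed pseudogenes, 6.06% (5.65 to 6.49%) at long noncoding RNA genes, 4.40% (3.32 to 5.70%) at microRNA genes, 4.02% (3.64 to 4.43%) at other pseudogenes and 0.697% (0.281 to 1.43%) at small nuclear RNA genes. These shares were not matched on gene length. Short genes have less sequence within the windows at their ends, so the order of the classes may reflect length.

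Duxf3, the mouse Dux gene that switches on 2-cell stage genes and a known target of DPPA2, lies at chromosome 10, 58229505 to 58233089. A peak over it, 58231784 to 58232891, was called in both lists, with its summit 1109 bp from the gene's nearer end and so outside the 1 kb window. Its pileup was 187 fragments (161 to 216) untreated and 305 (272 to 341) with adriamycin, 1.89 times (1.57 to 2.28) once scaled to the genome-wide background. That ratio ranked 2 among 92 shared peaks of over 60 times the background, of which 59 lay in high local background and whose median was 1.01. Over all 5603 shared peaks on the assembled chromosomes the median was 1.32 (quartiles 1.07 and 1.59), and in high local background, where the Dux peaks lie, it was 1.03 (0.928 and 1.16, 145 peaks). The neighbouring peak over LOC100504180, 58224243 to 58225282, had 156 (132 to 182) and 204 (177 to 234) fragments, a ratio of 1.52 (1.23 to 1.88) and rank 7, and that ratio is within the quartiles of all shared peaks. The local background at Duxf3 was 17.3 times the genome-wide value untreated and 26.3 times with adriamycin, and at the neighbouring peak 15.5 and 19.9 times. Where a library serves as its own background, these values include the peak's own fragments. They therefore do not show whether signal around the peaks, apart from the peaks themselves, was higher with adriamycin. The ratios and ranks given here are not corrected for local background. Dux lies in an array of near-identical copies, so reads can be shared between copies.

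The excess of germline and Wnt genes with adriamycin was set against 2 technical explanations. That open promoters in general carry peaks is argued against by the ribosomal protein genes, whose promoters are open in all cells: 1 of 10000 random lists, and 65 of 10000 matched on gene length, had as few members with a peak. A part played by openness stays open, since receptor and defensin families silent in most tissues were near 0 (Olfr 14 of 1110, Vmn 2 of 355, Defb 0 of 42), and Rnf, Fbxl and Zdhhc genes were above random lists. Matching on gene length took the random median for olfactory receptors from 177 to 54. The matched lists could include the receptors themselves, so that fall does not tell length from openness. Gene length is argued against by random lists matched on it, of which 12 of 10000 had as many members as the germline list and 53 as many as the Wnt list. CpG content of promoters was not tested and stays open, and the excess was uneven among related families: 7 of the 10 Fzd receptor genes had a peak, a family under the minimum of 15 genes set for the test by symbol, whereas genes of the stem Wnt had 3 of 19 (random median 3), Tex 5 of 39 (median 6) and Rhox 0 of 33, below random lists (18 of 10000 as few).

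In the adriamycin list 25.6% (23.5 to 27.8%) of the weakest 10% of peaks had a summit at a gene end, against 8.26% (6.96 to 9.70%) of the strongest 10%. Removing peaks in high local background could not have closed this gap. They were 263 of the 16229 adriamycin peaks (1.62%), while the strongest 10% held 1623. Without them the strongest 10% still had 8.20% (6.90 to 9.66%), against 20.7% (20.1 to 21.3%) of all remaining peaks. By the limit of 5 times the background, such peaks were too few to be the whole cause, and the removal tests nothing further. No biological explanation was tested, since the groups give none.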
